A study of Mus musculus with 39 samples.

How the data were processed

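RNA of colon and rectum of C57BL/6J mice was measured on 39 Agilent two-colour whole-genome arrays in 10 groups of age, tissue and housing, each against a common reference. Per the file headers, the scanner files hold the mean signal intensity of each spot and the median intensity of its local background in green (Cy3) and red (Cy5), and processed signal intensities that Feature Extraction 9.1.3.1 (22 arrays) or 9.5.3.1 (17 arrays) had background-subtracted and dye-normalized. The deposited value table holds log10 ratios of the same arrays, equal to the scanner's log ratio on every array once the sign was turned on the 12 arrays labelled with the sample in Cy3. Its columns are not centred across arrays, and its medians are 0 on 31 arrays and -0.00530 to 0.0279 on the others. 

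The direction of the table stays unknown. On 6 arrays the log ratio had the opposite sign to the signals of its own file, and the signals of 12 arrays opposed the labelled dye. The channel of the sample was therefore read on every array from 9 probes of Paneth cell genes, which belong to the small intestine of the reference, by 1 rule for all arrays, whole arrays turned. The smallest absolute median log2 ratio of these probes was 3.13. This reading departs from the labels and from the plan. It was chosen after the labelled fit had been seen and before any call of the turned fit, and every comparison is also given with the dyes as labelled and without the 12 arrays. Groups were not changed.

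Signals were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, with the data.table package (1.17.8), and normalized by loess within each array, with control spots at weight 0. Of 45018 features, 43379 were not controls and made up 41174 probes. Spots with an outlier flag were left out, 4 to 686 per array, saturated spots were kept, and spots of a probe were averaged. A probe was kept where it was well above background in the sample's channel on at least 3 arrays, which left 36652 probes. Each gene took the probe with the highest mean brightness, giving 24295 genes. Names came from the reference table by accession for 24646 probes, by symbol for 6321 and by synonym for 2471, and 7736 kept the name in the file. The 2 arrays with 1 RNA were averaged. 

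The log2 ratios of sample over reference of all 38 samples were fitted in limma with a term for each group and 1 for the dye, by exact least squares for each pattern of missing values, and tested with eBayes (two-sided). 12 contrasts were taken: rectum against colon at 5 stages, gnotobiotic against non-gnotobiotic mice in each tissue, the change of the rectum and colon difference with housing and from fetus to adult, and 3 age steps averaged over the tissues. Differences in the text carry standard errors. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes with a value. As read, fetal, 1-week and 4-week samples were all in Cy3, non-gnotobiotic 8-week samples all in Cy5, and gnotobiotic samples in both, with Cy5 on slide K alone, so the dye term was estimated from gnotobiotic arrays. 33 gene lists, fixed before the data were examined, were tested with camera on 22053 genes with an inter-gene correlation preset at 0.01, and again with an estimated correlation. Adjustment was over the lists of a comparison. Where a list's call is given, the count of members is over all genes tested, with the count adjusted over the list alone beside it.

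The genes named follow a rule fixed before the data were examined. It takes the 8 greatest differences each way in the 8-week tissue, gnotobiotic and age comparisons, the 5 greatest each way in the others, and up to 4 called members of each list, for genes with an approved-looking symbol (17677 genes). Rectum and colon genes among the greatest differences also had to point the same way in every pair. The text names a subset of these. Every gene named was above background on at least 1 array of each side of the comparison it is named for. Samples of the 2 tissues with the same number were checked for pairing by the correlation of their deviations from the group means across genes, which was 0.286 to 0.671 at 8 weeks, 0.184 to 0.816 in the fetus and 0.209 to 0.687 in gnotobiotic mice. These numbers were taken to pair the samples, from the data alone, and most pairs shared a slide. The 11 slides, 29 of whose arrays had been stripped and used again, are given letters. Slides holding both tissues were fitted as a block.

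The procedure was tested on simulated data with the same design, in which 200 genes were changed per comparison. Of genes changed 2-fold, 53.7% to 86.6% were called, and of those changed 4-fold 84.8% to 98.5%, none in the wrong direction, with 4 to 11 calls among unchanged genes. All 12 changed lists and 0 of 384 unchanged lists were called. The noise was independent, so effects of correlated genes or samples were not tested. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. No genome build or platform annotation was used, and no microarray file was left out.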

Results

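Transcript levels in the large intestine of C57BL/6J mice were measured on 39 two-colour oligonucleotide arrays, each carrying 1 sample and a common reference pooled from 4 RNAs of small intestine, colon and rectum. The 10 groups were colon and rectum at embryonic day 18.5, 1 week and 4 weeks (3 samples each), at 8 weeks (6 each), and in 8-week gnotobiotic mice, which live with a known microbial population or with none (4 each). In gnotobiotic colon 2 arrays carried the same RNA and were averaged, leaving 38 samples, and each RNA came from 1 to 8 animals. The labels of fetal and 1-week colon read rt. colon, an abbreviation left unresolved here, and those of other colon samples do not, so the site within the colon may differ with age. Younger samples and replicate 6 of each non-gnotobiotic 8-week group were whole organ, and the rest were mucosa. In the sample's channel 42.6% to 86.5% of spots were well above background (median 64.1%), and 32.7% to 93.2% in the reference channel.

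Which dye carried the sample was not settled by the labels. On 12 of the 27 arrays labelled Cy5, transcripts of Paneth cells, which lie in the small intestine and therefore in the reference, were bright in the channel that the label gave to the sample. All 18 pairs of such an array with another array of its group correlated below 0 across genes as labelled (-0.846 to -0.526), whereas other pairs of the same group correlated at 0.310 or more. The 12 arrays were replicates 1 and 2 of fetal and gnotobiotic samples and replicates 2 and 3 of 1-week samples, in both tissues. All directions below use the channel as read, which departs from the labels on these 12 arrays and was chosen after the labelled data had been seen. Counts with the dyes as labelled and without the 12 arrays stand beside each comparison. Without them 1 sample is left in each fetal and 1-week group, taken to vary like the other groups, and 2 in each gnotobiotic group. Values are log2 differences ± standard error.

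**Figure D1:**
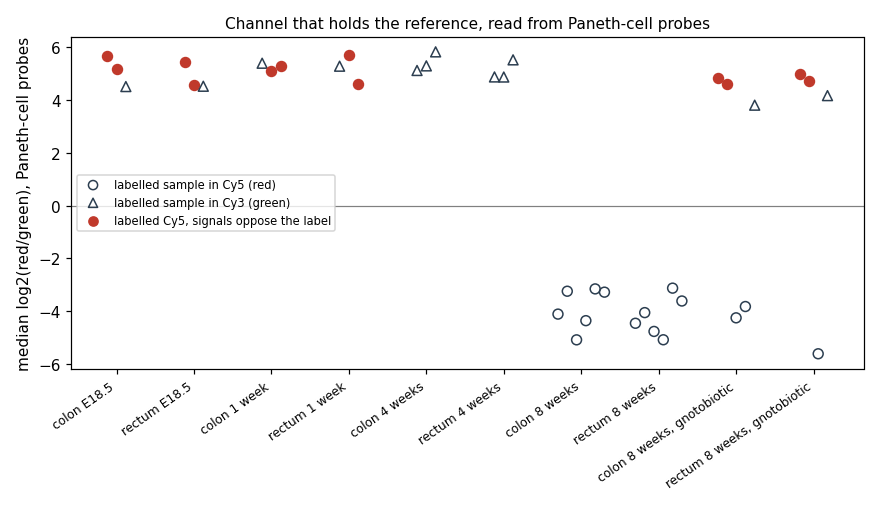
Median log2 red over green signal of 9 probes of Paneth cell genes on each of 39 arrays, by group (dimensionless). Filled red circles are the 12 arrays labelled as sample in Cy5 whose reference signal lay in red, and every array lay at least 3.13 from 0.

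The first comparison asked how adult rectum differed from adult colon, with 6 samples of each at 8 weeks. Rectum held far more of the posterior patterning genes Hoxd13 (5.16 ± 0.69) and Hoxb13 (4.28 ± 0.45), the former 35.7-fold, and less of the more anterior Hoxb7 (-3.66 ± 0.43) and Hoxb6 (-2.79 ± 0.34). In all, 8 of 18 measured posterior Hox genes were higher and 4 were lower (14 called over the list alone, adjusted p = 0.0492, adjusted p = 0.139 with an estimated correlation, adjusted p = 0.21 with the pair as a block, adjusted p = 0.113 with the slide as a block). Transport genes split: Atp12a (4.00 ± 0.44), the non-gastric proton/potassium pump, and Best2 (3.05 ± 0.23), an anion channel of goblet cells, were higher in rectum, while Slc9a3 (-3.13 ± 0.65), a sodium/proton exchanger of absorptive cells, was lower. 8 of 27 measured ion and water transport genes were higher and 4 were lower (15 called over the list alone, adjusted p = 0.0272, adjusted p = 0.268 with an estimated correlation, adjusted p = 0.0579 with the pair as a block, adjusted p = 0.0948 with the slide as a block). The largest differences the other way were Plet1 (-6.21 ± 0.34), 74.0-fold lower in rectum, and Nts (-5.86 ± 0.68), which encodes neurotensin. Sval1 (4.54 ± 0.69), Eno3 (3.67 ± 0.37), the muscle enolase, and Tgm3 (3.56 ± 0.36), a transglutaminase, were also among the genes most raised in rectum.

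The intestinal transcription factors Cdx2 (-3.48 ± 0.29) and Isx (-5.76 ± 0.39) and Tbx3 (-2.96 ± 0.33) were lower in rectum, and 4 of 21 measured gut patterning factors were lower and 1 was higher (6 called over the list alone, adjusted p = 0.000291, adjusted p = 0.00317 with an estimated correlation). Among hormone genes, Sct (-3.86 ± 0.20) (secretin) joined Nts, whereas Insl5 (2.21 ± 0.48), a hormone of distal colonic L cells, was higher in 5 of 6 pairs. 8 of 18 measured enteroendocrine genes were lower and 1 was higher (11 called over the list alone, adjusted p = 8.56e-12, adjusted p = 0.00317 with an estimated correlation). The secretory genes Muc2 (-1.57 ± 0.30), the main intestinal mucin, Spdef (-1.62 ± 0.18), a goblet cell transcription factor, and Retnlb (-3.32 ± 0.39) were lower, and 6 of 18 measured goblet cell and mucus genes were lower and 1 was higher (8 called over the list alone, adjusted p = 0.00177, adjusted p = 0.0394 with an estimated correlation). The antimicrobial genes Reg3b (-3.70 ± 0.50) and Ang4 (-3.17 ± 0.62) were lower too, although that list as a whole had 5 members lower and 4 higher of 22 measured and was not called (adjusted p = 0.481). Metabolic genes were lower as groups. The cytochromes P450 Cyp2c65 (-5.11 ± 0.53) and Cyp2c66 (-4.39 ± 0.38) led the xenobiotic list, in which 18 of 46 measured members were lower and 2 were higher (29 called over the list alone, adjusted p = 2.95e-11, adjusted p = 0.0394 with an estimated correlation). Pdk4 (-3.54 ± 0.41), a brake on glucose oxidation, was lower, and 10 of 25 measured fatty acid oxidation genes were lower and 3 were higher (15 called over the list alone, adjusted p = 8.99e-06, adjusted p = 0.0394 with an estimated correlation). Lymphocyte transcripts such as Ccl5 (-1.92 ± 0.44) and Gzma (-2.54 ± 0.72) were lower, and 11 of 26 measured T and NK cell genes were lower and 1 was higher (13 called over the list alone, adjusted p = 3.88e-06, adjusted p = 0.232 with an estimated correlation). Tmigd1 (-5.24 ± 0.72) was also lower.

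Of 24295 genes, 1774 passed an adjusted p of 0.05 in limma, 788 higher and 986 lower. The named genes passed at an adjusted p of at most 0.023. The pair numbers tracked together, and with the pair as a block 3170 genes were called, 1764 of the 1774 among them. A block for the slide gave 1738 calls, 1176 of the 1774 among them. Of 17 lists called, 5 held with an estimated correlation, and none held with that together with a pair or slide block. No array of these groups opposed its label, so the other readings moved only the estimate of the spread: limma called 915 genes with the dyes as labelled, 891 of the 1774 among them, and 1904 without the 12 arrays, 1578 among them. Replicate 4 of the colon stood apart from the other 5 for Eno3, Isx, Plet1, Sct and the goblet cell and fatty acid oxidation lists, and replicate 6 of the rectum for the xenobiotic list.

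**Figure D2:**
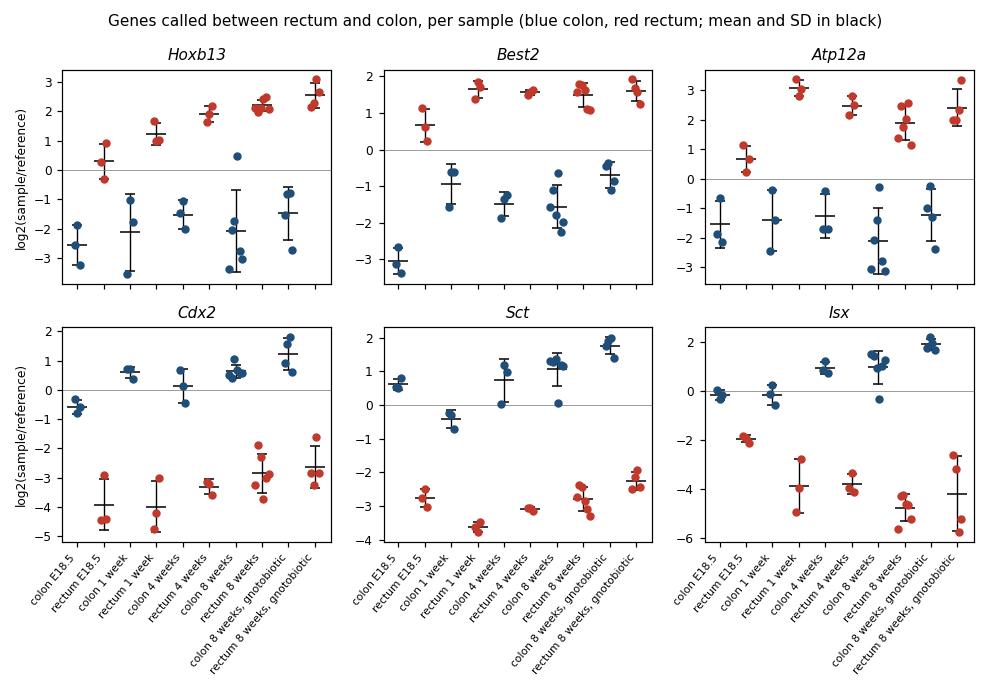
Log2 sample over reference ratio of genes that differed between rectum and colon, 1 point per sample, by stage. Colon is blue and rectum is red, bars are group means, and the 8-week difference was 4.28 for Hoxb13 and -3.48 for Cdx2.

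At embryonic day 18.5 the same question was asked before birth, in 3 whole-organ samples of each tissue. Fetal rectum held more transcripts of stratified squamous epithelium, the tissue of skin and anal canal: 13 of 28 measured squamous genes were higher (23 called over the list alone, adjusted p = 2.62e-42, adjusted p = 7.89e-05 with an estimated correlation). Examples were Ly6d (3.77 ± 0.68), Krt1 (3.08 ± 0.50) and Krtdap (3.23 ± 0.54) and Lor (3.09 ± 0.53), which encodes loricrin of the cornified envelope. Skeletal muscle transcripts moved with them: 5 of 22 measured skeletal muscle genes were higher (10 called over the list alone, adjusted p = 6.95e-14, adjusted p = 0.00189 with an estimated correlation), including Myh3 (1.96 ± 0.19), the embryonic myosin heavy chain, and Mylpf (2.23 ± 0.52). Absorptive genes were lower. 8 of 24 measured small intestinal enterocyte genes were lower (16 called over the list alone, adjusted p = 2.09e-20, adjusted p = 0.00537 with an estimated correlation), such as Fabp2 (-4.80 ± 0.72) and Apoa4 (-2.91 ± 0.53), which serve fat uptake and transport. Of the genes of suckling enterocytes, which take up milk protein, 10 of 21 measured members were lower (13 called over the list alone, adjusted p = 1.55e-24, adjusted p = 1.11e-06 with an estimated correlation), led by the receptor pair Cubn (-3.86 ± 0.92) and Amn (-3.03 ± 0.47).

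Patterning and secretory genes already differed. Hoxb13 (2.84 ± 0.64) was higher and Cdx2 (-3.35 ± 0.41) lower in fetal rectum. The channel gene Best2 (3.72 ± 0.32), Sval1 (4.18 ± 0.98) and the goblet cell gene Clca1 (2.88 ± 0.60) were higher, and 2 of 18 measured goblet cell and mucus genes were higher (6 called over the list alone, adjusted p = 4.52e-09, adjusted p = 0.000104 with an estimated correlation). The hormone genes Sct (-3.39 ± 0.28) and Gcg (-1.72 ± 0.39) were lower, and 2 of 18 measured enteroendocrine genes were lower (5 called over the list alone, adjusted p = 1.53e-10, adjusted p = 0.00283 with an estimated correlation). In the transport list 2 of 27 measured members were higher (8 called over the list alone, adjusted p = 1.29e-08, adjusted p = 0.00278 with an estimated correlation), and in the fatty acid oxidation list 3 of 25 measured members were lower (5 called over the list alone, adjusted p = 8.96e-07, adjusted p = 0.0139 with an estimated correlation). Meltf (-3.63 ± 0.30), melanotransferrin, was lower as well. Of 24292 genes, 293 passed an adjusted p of 0.05 in limma, 159 higher and 134 lower. The named genes passed at an adjusted p of at most 0.0262. With the pair as a block 528 genes were called, and 533 with the slide as a block. Median centring or the compared groups alone gave far fewer (given below). Of 15 lists called, 9 held with an estimated correlation, 7 with that and the pair as a block (small intestinal enterocyte genes then had an adjusted p of 0.0584), and 8 with that and the slide as a block. Labelled dyes gave 0 calls in limma (176 at an unadjusted p under 0.05) and the same direction for 46 of the 293 genes. Leaving out the 12 arrays gave 498 calls, 152 of the 293 among them, from 1 sample per tissue. The count ranged from 135 without colon replicate 1 to 495 without rectum replicate 2.

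At 1 week, in 3 whole-organ samples of each tissue from mice of suckling age, the contrast of patterning genes was again large: Hoxb13 (3.34 ± 0.64) was higher and Cdx2 (-4.58 ± 0.41) and Isx (-3.74 ± 0.55) were lower in rectum. The transport genes Atp12a (4.47 ± 0.62) and Best2 (2.59 ± 0.32) were higher, and 3 of 27 measured transport genes were higher (9 called over the list alone, adjusted p = 0.000173, adjusted p = 0.0802 with an estimated correlation). The squamous genes Krt5 (2.38 ± 0.41), a basal keratin, and Lor (3.27 ± 0.53) were higher, and 4 of 28 measured squamous genes were higher (11 called over the list alone, adjusted p = 1.67e-13, adjusted p = 0.0627 with an estimated correlation). The acute-phase gene Saa1 (2.73 ± 0.46) was higher. The hormone gene Sct (-3.21 ± 0.28) was lower, and 2 of 18 measured enteroendocrine genes were lower (7 called over the list alone, adjusted p = 9.52e-14, adjusted p = 0.00252 with an estimated correlation). Cyp2c65 (-3.82 ± 0.74) was lower, and in the xenobiotic list 3 of 46 measured members were lower (10 called over the list alone, adjusted p = 0.00238, adjusted p = 0.466 with an estimated correlation). Of 24292 genes, 96 passed an adjusted p of 0.05 in limma, 44 higher and 52 lower. The named genes passed at an adjusted p of at most 0.0078. The slide as a block gave 169 calls, and the enteroendocrine shift had an adjusted p of 0.026 with that and an estimated correlation. Read as labelled, the arrays gave 0 genes in limma (139 at an unadjusted p under 0.05), with 8 of the 96 in the same direction. The arrays without the 12 gave 221, 41 of the 96 among them, from 1 sample per tissue. Without replicate 1 of the rectum 60 were called, and far fewer with median centring or the compared groups alone.

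At 4 weeks, past the usual age of weaning, 3 whole-organ samples of each tissue were compared. Rectum held more Fxyd4 (4.29 ± 0.77), a regulator of the sodium pump, Atp12a (3.75 ± 0.62) and Best2 (3.06 ± 0.32), and 3 of 27 measured transport genes were higher (5 called over the list alone, adjusted p = 0.0362, adjusted p = 0.392 with an estimated correlation, adjusted p = 0.0638 with the slide as a block, the same sign within 1 of 2 slides), with a mean of -0.00653 under median centring. Hoxb13 (3.43 ± 0.64) was higher, and Plet1 (-5.21 ± 0.48), Isx (-4.76 ± 0.55) and Cdx2 (-3.44 ± 0.41) were lower. The fat-binding gene Fabp2 (-4.95 ± 0.64) and the mucin Muc2 (-2.23 ± 0.42) were lower in rectum. Reg3g (-3.38 ± 0.53), an antimicrobial lectin, was lower, and 5 of 22 measured antimicrobial and inflammation genes were lower and 1 was higher (9 called over the list alone, adjusted p = 0.0228, adjusted p = 0.358 with an estimated correlation, adjusted p = 0.0856 with the slide as a block, a mean of -0.34 and a median of 0.03). Sct (-3.82 ± 0.28) was lower, and 5 of 18 measured enteroendocrine genes were lower (7 called over the list alone, adjusted p = 2.41e-10, adjusted p = 0.0131 with an estimated correlation). With Cyp2c65 (-4.67 ± 0.74) in the lead, 8 of 46 measured xenobiotic metabolism genes were lower (9 called over the list alone, adjusted p = 2.97e-10, adjusted p = 0.0919 with an estimated correlation). Of 24294 genes, 248 passed an adjusted p of 0.05 in limma, 123 higher and 125 lower. The named genes passed at an adjusted p of at most 0.00335. Blocking by slide, 503 genes were called, and the enteroendocrine shift, the only list shift called with an estimated correlation, was not called with both (adjusted p = 0.111). No array of these groups opposed its label, so here too only the estimate of the spread moved: limma called 0 genes with the dyes as labelled (816 at an unadjusted p under 0.05) and 275 without the 12 arrays, 199 of the 248 among them. Without colon replicate 3 the count was 147, and it also fell with median centring or the compared groups alone.

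In gnotobiotic mice the rectum and colon were compared to learn which differences were present under that housing (4 mucosal samples each). The labels leave open whether replicate 3 shares an animal with the pool of replicate 2, in which case the 4 are not all independent. Hoxb13 (4.02 ± 0.55) was again higher and Isx (-6.12 ± 0.47) and Cdx2 (-3.86 ± 0.35) and Hoxb6 (-3.16 ± 0.42) were lower in rectum. Among transport genes Aqp8 (4.27 ± 0.49), a water channel, Scnn1g (3.54 ± 0.41), a subunit of the epithelial sodium channel, and Atp12a (3.63 ± 0.54) were higher, and 8 of 27 measured transport genes were higher and 2 were lower (11 called over the list alone, adjusted p = 0.0062, adjusted p = 0.226 with an estimated correlation). Sval1 (5.19 ± 0.85) was the most raised of the named genes. The hormone genes Nts (-5.70 ± 0.83) and Sct (-4.02 ± 0.24) and Cck (-3.54 ± 0.44) (cholecystokinin) were lower, and 7 of 18 measured enteroendocrine genes were lower (9 called over the list alone, adjusted p = 1.11e-12, adjusted p = 0.00413 with an estimated correlation). Fat cell genes moved with the tissue as well: Cfd (-5.98 ± 1.02) (adipsin) and Fabp4 (-4.08 ± 0.64) were lower in rectum, and 6 of 12 measured adipose genes were lower (7 called over the list alone, adjusted p = 1.26e-09, adjusted p = 0.131 with an estimated correlation). Cyp4b1 (-5.24 ± 0.61) was lower, and in the xenobiotic list 14 of 46 measured members were lower and 1 was higher (18 called over the list alone, adjusted p = 4.19e-05, adjusted p = 0.287 with an estimated correlation). Of 24295 genes, 1264 passed an adjusted p of 0.05 in limma, 543 higher and 721 lower. The named genes passed at an adjusted p of at most 0.00025. With the pair as a block 2573 genes were called, and 2733 with the slide as a block. The enteroendocrine shift, the only list shift called with an estimated correlation, was not called with that together with a block of the pair (adjusted p = 0.207) or the slide (adjusted p = 0.0678). With the dyes as labelled, limma called 0 genes (365 at an unadjusted p under 0.05), and 1060 of the 1264 pointed the same way, but 4 of 14 named genes changed sign. Without the 12 arrays, 1437 were called, 872 of the 1264 among them. Without replicate 3 of either tissue, the samples on slide K, 510 genes were called.

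**Figure D3:**
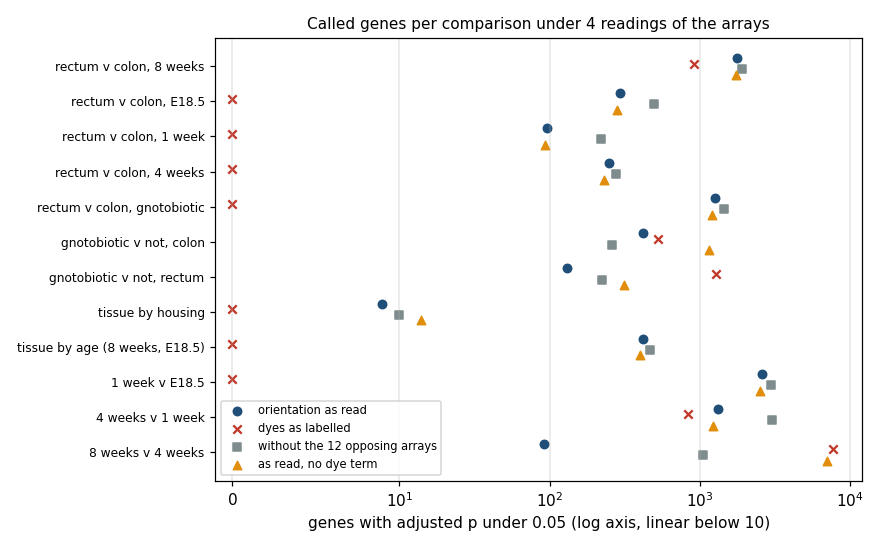
Number of genes with an adjusted p under 0.05 in each of 12 comparisons, on a log axis that is linear below 10. Markers are 4 readings of the same arrays, and the 8-week comparison of rectum with colon gave 1774 genes with channels as read and 915 with dyes as labelled.

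The colon of gnotobiotic mice was set against that of non-gnotobiotic mice, 4 samples against 6, to see what differed with housing. No slide held both, so housing cannot be told from slide. The colon of gnotobiotic mice held less of the host-defence genes Ang4 (-4.22 ± 0.95), Retnlb (-2.98 ± 0.60) and Duoxa2 (-2.32 ± 0.51), the maturation factor of an oxidase that makes hydrogen peroxide, and more of the acute-phase gene Saa2 (2.35 ± 0.58). Of the goblet cell and mucus list, 1 of 18 measured members was lower (6 called over the list alone, adjusted p = 3.69e-05, adjusted p = 0.00889 with an estimated correlation), the member being Retnlb. The water channel Aqp8 (-3.29 ± 0.61) and the gasdermins Gsdmc (-2.53 ± 0.34) and Gsdmc3 (-2.38 ± 0.33) were lower. Drug-metabolism genes went both ways: Cyp2c55 (-2.84 ± 0.52) and Gstm1 (-1.50 ± 0.31) were lower and Cyp4f14 (1.35 ± 0.29) was higher, and the xenobiotic list, with 4 lower and 1 higher of 46 measured, was not called (adjusted p = 0.297). Pdk4 (-2.48 ± 0.63) was lower, in a fatty acid oxidation list that, with 1 lower and 2 higher of 25 measured, was not called (adjusted p = 0.529). Metallothioneins, which bind zinc and copper, were higher: Mt1 (2.56 ± 0.41) and Mt2 (3.85 ± 0.59). The lysosomal sialidase Neu1 (1.59 ± 0.26), the clock-controlled factor Dbp (2.88 ± 0.68) and the fat cell gene Fabp4 (3.32 ± 0.81) were higher too, and 1 of 12 measured adipose genes was higher (2 called over the list alone, adjusted p = 0.00131, adjusted p = 0.924 with an estimated correlation). Cell-cycle genes Ccnb2 (-1.65 ± 0.35), Cdc20 (-1.46 ± 0.36) and Pcna (-0.87 ± 0.20) were lower, and 3 of 22 measured proliferation genes were lower (5 called over the list alone, adjusted p = 7.53e-11, adjusted p = 0.53 with an estimated correlation).

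Of 24295 genes, 421 passed an adjusted p of 0.05 in limma, 275 higher and 146 lower. For 18 of the 19 named genes every gnotobiotic sample with a value (3 for Cyp2c55, Cyp4f14 and Gsdmc3, 4 otherwise) lay on the called side of the non-gnotobiotic mean, and Neu1 had 3 of 4 there. The highest adjusted p among them was 0.0361. Labelled dyes gave 526 calls in limma and the same direction for 322 of the 421 genes. However, 11 of 19 named genes changed sign, such as Ang4 (4.18) and Mt2 (-1.50). Leaving out the 12 arrays gave 260 calls, 196 of the 421 among them. Every non-gnotobiotic 8-week array was read in Cy5, and of gnotobiotic mice only those on slide K. The dye term thus rested on replicate 3 of each tissue. Without colon replicate 3 the count was 16, and with a random slide block it also fell far. Without the dye term it was 1148, of which 259 were among the 421, and Dbp (1.66), Saa2 (1.42), Neu1 (0.42), Pdk4 (-1.46) and Cdc20 (-0.86) were then not called. Replicate 4 of the non-gnotobiotic colon stood apart for Aqp8 and Saa2, and replicate 3 of the gnotobiotic colon for Neu1.

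**Figure D4:**
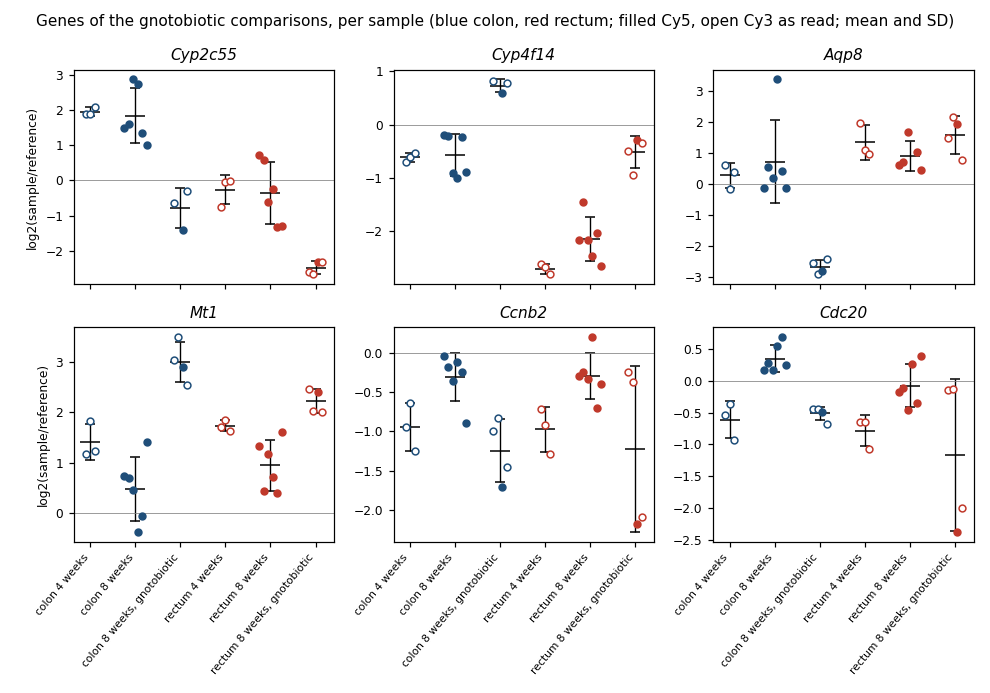
Log2 sample over reference ratio of genes that differed between gnotobiotic and non-gnotobiotic mice, 1 point per sample at 8 weeks. Colon is blue and rectum is red, bars are group means, and the gnotobiotic difference of Cyp2c55 was -2.84 in colon and -2.36 in rectum.

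In rectum the same contrast of 4 gnotobiotic with 6 non-gnotobiotic samples was led by Cyp2c55 (-2.36 ± 0.52), a cytochrome P450 of the colon, which was lower. Genes of cell division were lower: Mki67 (-1.88 ± 0.36), Birc5 (-1.74 ± 0.40), Cdc20 (-1.69 ± 0.36), Plk1 (-1.67 ± 0.30) and Ccnb2 (-1.64 ± 0.35), and 5 of 22 measured proliferation genes were lower (14 called over the list alone, adjusted p = 8.33e-20, adjusted p = 0.166 with an estimated correlation). The selenoprotein gene Selenom (-1.76 ± 0.26) was lower. Higher were Cyp4f14 (1.69 ± 0.29), a fatty acid hydroxylase, Sord (1.53 ± 0.35), sorbitol dehydrogenase, Crim1 (1.52 ± 0.27) and Chd4 (1.44 ± 0.19), a chromatin remodeller. Of 24295 genes, 131 passed an adjusted p of 0.05 in limma, 78 higher and 53 lower. All 4 gnotobiotic samples lay on the called side of the non-gnotobiotic mean for 9 of the 11 named genes, and at least 3 of 4 for the others. The highest adjusted p among them was 0.0408. Read as labelled, the arrays gave 1272 genes in limma, with 112 of the 131 in the same direction, but 2 of 11 named genes changed sign. The arrays without the 12 gave 225, 77 of the 131 among them. Here too housing went with slide and the dye term rested on slide K. The count fell far with a random slide block, and was 4 without rectum replicate 3 and 313 without the dye term. Of the 131, 32 were called without that term, and Chd4 (0.56), Mki67 (-0.96) and Ccnb2 (-0.93) were not. Between the tissues, 83 genes were called in the same direction, 67 higher and 16 lower. The comparisons shared the dye estimate, and 82 of these genes had the opposite sign in the step from 4 to 8 weeks.

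The test of whether the rectum and colon difference itself depended on housing concerned the samples of the 4 groups of 8-week mice. In gnotobiotic mice the balance shifted towards rectum for Aqp8 (4.09 ± 0.64), the gasdermins Gsdmc (2.00 ± 0.34) and Gsdmc3 (1.87 ± 0.35), Sdhb (1.44 ± 0.26), a subunit of succinate dehydrogenase, and Casp6 (1.12 ± 0.20), a caspase. It shifted towards colon for Hmga1 (-1.30 ± 0.24), a chromatin protein, Deptor (-1.23 ± 0.21), an inhibitor of mTOR, Oip5os1 (-1.06 ± 0.21) and Evpl (-0.99 ± 0.19), envoplakin of the cornified envelope. As a set, B cell and plasma cell genes shifted towards rectum by a mean of 0.58 (adjusted p = 8.86e-06, adjusted p = 0.748 with an estimated correlation), and goblet cell genes by 0.37 (adjusted p = 0.00131, adjusted p = 0.0549 with an estimated correlation). Of 24295 genes, 9 passed an adjusted p of 0.05 in limma, 5 higher and 4 lower. These 9 genes are all the calls, at an adjusted p of at most 0.0494. Under the labelled dyes 0 genes were called by limma (811 at an unadjusted p under 0.05), and the direction was kept by 7 of the 9. Without the 12 arrays, 10 were called, 1 of the 9 among them. Replicate 4 of the 8-week colon stood apart for Aqp8, and replicate 3 of the gnotobiotic colon for Hmga1. Without replicate 3 of either gnotobiotic tissue limma called 0 genes (831 at an unadjusted p under 0.05), without colon replicate 6 of non-gnotobiotic mice 146, and with the slide as a block 483.

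Whether the rectum and colon difference changed between fetal and adult life was tested on the samples of both stages. All fetal samples but only replicate 6 of the adult ones were whole organ, so stage is poorly told from preparation. The colon labels differ, so stage cannot be told from site. The greatest change was Plet1 (-7.60 ± 0.59), lower in adult rectum but with a fetal difference of 1.39 that was not called, and Isx (-3.96 ± 0.67) changed the same way. As a list, goblet cell genes were higher in fetal rectum and lower in adult rectum. Of these Clca1 (-3.69 ± 0.74) and Retnlb (-3.32 ± 0.67) changed the most, and 5 of 18 measured goblet cell and mucus genes were lower (9 called over the list alone, adjusted p = 9.79e-11, adjusted p = 5.47e-05 with an estimated correlation). The squamous excess of fetal rectum was smaller in the adult for Ly6d (-4.03 ± 0.84) and Krt1 (-2.54 ± 0.61), the latter turning to 0.50 with Agilent's processed signals, and 9 of 28 measured squamous genes were lower (18 called over the list alone, adjusted p = 1.85e-18, adjusted p = 0.00946 with an estimated correlation). Absorptive genes moved the other way, since the deficit of fetal rectum lessened for Apoa4 (2.75 ± 0.65) and for the lysosomal enzymes Neu1 (1.39 ± 0.32) and Glb1 (1.37 ± 0.29), and 2 of 21 measured suckling enterocyte genes were higher (13 called over the list alone, adjusted p = 1.11e-06, adjusted p = 0.00946 with an estimated correlation). Cyp2c40 (5.51 ± 0.44) and Hoxd10 (2.67 ± 0.51) shifted towards the adult rectum. Of 24292 genes, 418 passed an adjusted p of 0.05 in limma, 160 higher and 258 lower. The named genes passed at an adjusted p of at most 0.0225. With the dyes as labelled, limma called 0 genes (1265 at an unadjusted p under 0.05), and 338 of the 418 pointed the same way, but 6 of 11 named genes changed sign. Without the 12 arrays, 463 were called, 146 of the 418 among them, from 1 fetal sample per tissue. With the slide as a block 544 genes were called, with the pair as a block 1180, and without colon replicate 1 of the fetal samples 224. Replicate 1 of the 8-week rectum stood apart for Krt1.

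The step from embryonic day 18.5 to 1 week, averaged over both tissues (6 samples against 6), asked what changed around birth. Among the greatest falls were Afp (-5.28 ± 0.37), alpha-fetoprotein, Fgg (-3.96 ± 0.49), a fibrinogen chain, and Fabp1 (-4.90 ± 0.64), the liver fatty acid binding protein. Red-cell genes fell with them: Slc4a1 (-3.09 ± 0.20) is the band 3 anion exchanger, Alas2 (-2.71 ± 0.23) makes haem, and 11 of 13 measured erythroid genes were lower (11 called over the list alone, adjusted p = 4.64e-19, adjusted p = 0.00918 with an estimated correlation). Slc25a37 (-5.08 ± 0.16), a mitochondrial iron importer, fell. The neutrophil gene S100a9 (-3.88 ± 0.50) fell. The fetal growth gene Meg3 (-2.19 ± 0.30) fell, and 9 of 16 measured imprinted and fetal growth genes were lower (13 called over the list alone, adjusted p = 7.23e-10, adjusted p = 0.00918 with an estimated correlation). The division marker Mki67 (-1.36 ± 0.23) fell, and 11 of 22 measured proliferation genes were lower (14 called over the list alone, adjusted p = 7.23e-10, adjusted p = 0.204 with an estimated correlation). Of the cholesterol synthesis list, 8 of 22 measured members were lower (12 called over the list alone, adjusted p = 8.05e-05, adjusted p = 0.127 with an estimated correlation).

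The water channel Aqp8 (3.68 ± 0.40) and the sodium/proton exchanger Slc9a2 (2.08 ± 0.27) were higher at 1 week, and 11 of 27 measured transport genes were higher and 1 was lower (17 called over the list alone, adjusted p = 1.33e-07, adjusted p = 0.00918 with an estimated correlation). Nqo1 (2.70 ± 0.24) and Cyp2c65 (2.48 ± 0.53) rose, and in the xenobiotic list 14 of 46 measured members were higher and 1 was lower (19 called over the list alone, adjusted p = 1.62e-05, adjusted p = 0.232 with an estimated correlation). Dmbt1 (3.27 ± 0.15), a mucosal defence glycoprotein, rose, as did Ctss (3.01 ± 0.22) and Cd74 (2.23 ± 0.42) of antigen presentation, and 3 of 11 measured MHC class II presentation genes were higher (5 called over the list alone, adjusted p = 0.00352, adjusted p = 0.356 with an estimated correlation). Klk1 (1.64 ± 0.17) was higher, and 5 of 18 measured goblet cell and mucus genes were higher (6 called over the list alone, adjusted p = 0.00352, adjusted p = 0.0685 with an estimated correlation). Smooth muscle gained Des (1.99 ± 0.57) (desmin), and 6 of 17 measured smooth muscle genes were higher (12 called over the list alone, adjusted p = 8.05e-05, adjusted p = 0.347 with an estimated correlation), whereas skeletal muscle lost Mylpf (-2.20 ± 0.35), and 7 of 22 measured skeletal muscle genes were lower (9 called over the list alone, adjusted p = 0.0164, adjusted p = 0.356 with an estimated correlation). Of 24289 genes, 2579 passed an adjusted p of 0.05 in limma, 1236 higher and 1343 lower. For all 19 named genes the 6 samples of 1 week lay on the called side of the fetal mean of their tissue, at an adjusted p of at most 0.022. Labelled dyes gave 0 calls in limma (537 at an unadjusted p under 0.05) and the same direction for 634 of the 2579 genes. Leaving out the 12 arrays gave 2981 calls, 1396 of the 2579 among them, from 1 sample per group. With the slide as a random block 1023 genes were called.

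From 1 to 4 weeks, over weaning, 6 samples were set against 6. The 1-week but not the 4-week colon is labelled rt. colon, so site may differ along with age. The carbonic anhydrases Car4 (4.05 ± 0.34) and Car1 (2.23 ± 0.33), the surface keratin Krt20 (2.81 ± 0.32), Sult1a1 (2.94 ± 0.21), a sulfotransferase, Cyp2c55 (2.88 ± 0.33) and Sectm1b (3.01 ± 0.24) rose. In the transport list 7 of 27 measured members were higher (9 called over the list alone, adjusted p = 0.00151, adjusted p = 0.255 with an estimated correlation), and in the xenobiotic list 9 of 46 measured members were higher and 2 were lower (15 called over the list alone, adjusted p = 0.00691, adjusted p = 0.759 with an estimated correlation). Mucus and secretion genes rose together, with Zg16 (2.23 ± 0.43), Clca1 (1.85 ± 0.43) and Muc2 (1.38 ± 0.30), and 9 of 18 measured goblet cell and mucus genes were higher (10 called over the list alone, adjusted p = 0.000203, adjusted p = 0.0294 with an estimated correlation). Pigr (1.84 ± 0.41), the receptor that carries immunoglobulin A into the lumen, rose, and 3 of 22 measured antimicrobial and inflammation genes were higher (7 called over the list alone, adjusted p = 0.00691, adjusted p = 0.345 with an estimated correlation). The proteasome gene Psmb8 (1.28 ± 0.30) rose, and 3 of 27 measured interferon response genes were higher (3 called over the list alone, adjusted p = 0.000166, adjusted p = 0.764 with an estimated correlation). The early-response factors Junb (1.25 ± 0.20) and Klf4 (1.30 ± 0.27) were higher, and 6 of 19 measured immediate early genes were higher (6 called over the list alone, adjusted p = 0.000397, adjusted p = 0.255 with an estimated correlation). Growth genes fell: Mest (-2.07 ± 0.44), Grb10 (-1.65 ± 0.35) and Dlk1 (-1.47 ± 0.41) are imprinted, Mdk (-2.33 ± 0.20) is a fetal growth factor, and 7 of 16 measured imprinted and fetal growth genes were lower (8 called over the list alone, adjusted p = 2.37e-05, adjusted p = 0.0944 with an estimated correlation). Matrix genes Col5a1 (-1.79 ± 0.42), Col3a1 (-1.49 ± 0.36) and Postn (-1.67 ± 0.36) fell, and 7 of 24 measured matrix and fibroblast genes were lower (11 called over the list alone, adjusted p = 7.41e-09, adjusted p = 0.345 with an estimated correlation). Pcna (-0.95 ± 0.13) fell, and 3 of 22 measured proliferation genes were lower (3 called over the list alone, adjusted p = 0.000293, adjusted p = 0.759 with an estimated correlation).

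Of 24292 genes, 1315 passed an adjusted p of 0.05 in limma, 774 higher and 541 lower. For 19 of 21 named genes every 4-week sample with a value (5 for Mest, 6 otherwise) lay on the called side of the 1-week mean of their tissue, and at least 5 did for the others. The highest adjusted p among them was 0.0262. Read as labelled, the arrays gave 828 genes in limma, with 1185 of the 1315 in the same direction, but 2 of 21 named genes changed sign. The arrays without the 12 gave 3026, 685 of the 1315 among them, from 1 sample per tissue at 1 week. With the slide as a fixed block 3099 genes were called, and with a random slide block 1452.

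**Figure D5:**
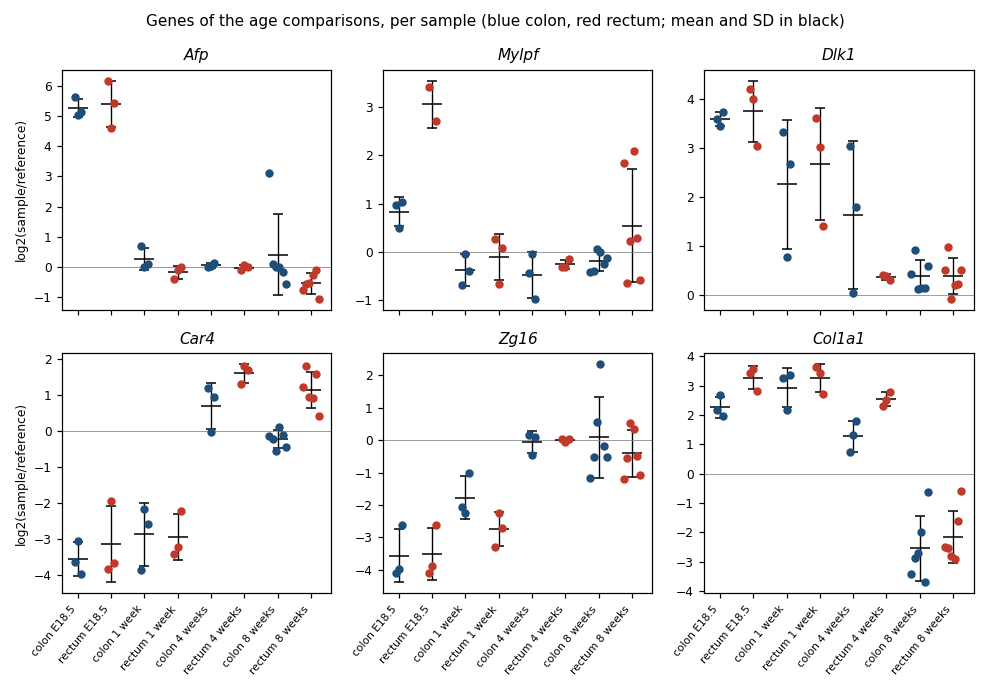
Log2 sample over reference ratio of genes that changed with age, 1 point per sample, from embryonic day 18.5 to 8 weeks. Colon is blue and rectum is red, bars are group means, and the step from embryonic day 18.5 to 1 week was -5.28 for Afp.

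From 4 to 8 weeks, 12 samples were set against 6. Connective tissue genes were far lower at 8 weeks: the collagens Col1a1 (-4.66 ± 0.82), Col3a1 (-4.46 ± 0.60) and Col1a2 (-4.34 ± 0.67), Sparc (-4.44 ± 0.58), Postn (-3.81 ± 0.59) and Dcn (-3.62 ± 0.68), and 6 of 24 measured matrix and fibroblast genes were lower (21 called over the list alone, adjusted p = 1.07e-24, adjusted p = 0.104 with an estimated correlation). Smooth muscle genes Tpm2 (-3.71 ± 0.82) and Actg2 (-2.50 ± 0.56) were lower, and 2 of 17 measured smooth muscle genes were lower (14 called over the list alone, adjusted p = 2.1e-15, adjusted p = 0.111 with an estimated correlation). The 4-week samples were whole organ and 10 of the 12 samples of 8 weeks were mucosa, and only the 2 whole-organ samples of replicate 6 told age from preparation. In whole-organ replicate 6 of the colon Col3a1 and Tpm2 stood apart from the 5 mucosal samples. Cpe (-2.82 ± 0.65), a hormone-processing enzyme, was lower. Ccnb2 (1.61 ± 0.37), a cyclin, and Rpl31 (1.17 ± 0.25) were higher, and 1 of 22 measured proliferation genes was higher (5 called over the list alone, adjusted p = 1.62e-06, adjusted p = 0.517 with an estimated correlation). Of 24294 genes, 92 passed an adjusted p of 0.05 in limma, 11 higher and 81 lower. For 10 of the 11 named genes all 12 samples lay on the called side of the 4-week mean, and Rpl31 had 6 of 12 there. The highest adjusted p among them was 0.0485. Under the labelled dyes 7718 genes were called by limma, and the direction was kept by 75 of the 92. Without the 12 arrays, 1044 were called, 57 of the 92 among them. All 4-week samples were read in Cy3 and all 8-week ones in Cy5, so the step rested on the dye term and slide K. Without that term 7047 genes were called, 42 of the 92 among them, and Rpl31 differed by 0.0105, not called. Ccnb2 differed by 0.66 without it, -0.22 as labelled and 0.83 without the 12 arrays, not called in the latter 2. The count was 877 with preparation as a term, 163 without colon replicate 6 of 8 weeks, and 50, 49 and 51 without colon replicate 3, rectum replicate 2 and rectum replicate 3 of 4 weeks. Almost no calls were left with the replicate number or the slide as a random block (counts given below).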

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

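The tests of the first 3 patterns below were chosen after the results had been seen. The splits of the samples and the tests of differences between groups were chosen before the data were examined.

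Of 221 sets of 4 to 6 samples tested for a sample apart from the others, 16 had one, where chance gives about 1 in 20, or 11. The gap from that sample to the nearest other in log2 ratio is given as a share of the range of the group. In 8-week colon replicate 4 it was 0.805 for Aqp8, 0.775 for Eno3, 0.689 for Isx, 0.67 for Plet1, 0.706 for Saa2, 0.837 for Sct, 0.721 for the mean of the fatty acid oxidation list and 0.677 for the mean of the goblet cell and mucus list. In 8-week colon replicate 6 it was 0.628 for Ccnb2, 0.691 for Col3a1 and 0.656 for Tpm2. In gnotobiotic colon replicate 3 it was 0.876 for Hmga1 and 0.947 for Neu1. In 8-week rectum replicate 1 it was 0.773 for Krt1 and 0.693 for the mean of the stratified squamous epithelium list. In 8-week rectum replicate 6 it was 0.739 for the mean of the xenobiotic metabolism list. Replicate 6 of the 8-week colon was the whole-organ sample of its group.

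The rectum and colon difference changed with housing for 9 genes, a tested difference: Aqp8 (4.09), Gsdmc (2.00), Gsdmc3 (1.87), Sdhb (1.44), Casp6 (1.12), Hmga1 (-1.30), Deptor (-1.23), Oip5os1 (-1.06) and Evpl (-0.99). It changed between fetus and adult, where preparation changed too, for 418 genes, among them Plet1 (-7.60), Isx (-3.96), Ly6d (-4.03), Krt1 (-2.54), Clca1 (-3.69), Retnlb (-3.32), Apoa4 (2.75), Neu1 (1.39), Glb1 (1.37), Cyp2c40 (5.51) and Hoxd10 (2.67), and the change of the list means was -1.18 for goblet cell and mucus, 0.71 for neonatal suckling enterocyte and -1.39 for stratified squamous epithelium.

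The signals of 12 arrays ran opposite to their labelled dye. A biological difference of these samples from their own group is argued against: pairs of such an array with another of its group correlated at -0.526 or lower as labelled. Wrong dye labels and exchanged channel columns, with the labels right, stay open and cannot be told apart. Both make every such pair correlate below 0 as labelled, as 18 of 18 did. The log ratio opposed the signals of its own file on 4 of the 12 arrays, and an exchange before the log ratio was written leaves no such sign.

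In gnotobiotic mice 83 genes were called in the same direction in both tissues, 67 higher and 16 lower (0.883 and 0.319 expected from independent lists). An error of the dye estimate, carried by slide K, stays open: it cancels in the difference of Cy3 gnotobiotic samples from 4-week samples, whose median, signed by the call, was 0.0366 (quartiles -0.0568 and 0.218), against a gnotobiotic difference of 1.16 (0.497 without the dye term). Simulated unchanged samples with independent noise gave 0 calls of both tissues, so such an error would have to exceed independent noise, as one shared by a slide could. Housing that lessens a change between 4 and 8 weeks gives the same median and stays open too, because 82 of the 83 had the opposite sign in that step, as both explanations give. Across genes the differences of the tissues correlated at 0.622 against 0.473 simulated with no effect (covariance 0.0802 against 0.0446), and genes are not independent replicates. Cyp2c55 and Cyp4f14, singled out after their values were seen, had 8-week steps of 0.22 and 0.23, small beside their gnotobiotic differences (-2.84 and 1.35 in colon).

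Squamous and skeletal muscle transcripts were higher in fetal rectum. A single rectum sample that held skin and muscle is argued against, since for both lists 9 of 9 comparisons of a rectum with a colon sample had the higher list mean in rectum. A change of the epithelium alone is argued against by the 5 skeletal muscle genes called. Tissue next to the rectum, taken with every fetal rectum, and development of the anal canal as part of the organ stay open and cannot be told apart, since both raise these transcripts in every sample: 45 of 50 members of both lists were higher in rectum.

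The samples were also split otherwise into groups of the same sizes. In brackets are the splits with as many calls, the real one included, and the real count against the highest of the others. Chance could be excluded for rectum and colon at 8 weeks (1 of 100, 1774 against 910) and the step to 4 weeks (1 of 100, 1315 against 1144). It could be too for the change of the tissue difference from fetus to adult (1 of 100, 418 against 162). Few splits called as many for gnotobiotic colon (2 of 100, 421 against 496) and the step to 8 weeks (2 of 100, 92 against 398). There this cannot exclude chance, since other splits mix the dyes and an error of the dye estimate falls on the real one. Nor can the splits exclude chance for the change of the tissue difference with housing (4 of 100, 9 against 600). The count was 1 split of the draw short of 1 in 20, and other splits mix the dyes and the housing. Among splits that keep each pair together, tried after the results had been seen, 2 of 100 called as many for the change with housing (9 against 12) and 1 of 84 for that from fetus to adult (418 against 48). The former rested on replicate 3 of the gnotobiotic samples, as given above. By the count of calls chance could not be excluded for gnotobiotic rectum (5 of 100 splits, 131 against 2513) or for rectum and colon in gnotobiotic mice (2 of 35, 1264 against 3111). The latter split set the samples of slide J against the rest, and with the slide as a block the tissue difference there had 2733 calls. Across genes that tissue difference correlated at 0.73 with the 8-week one, which comes from other samples, against at most 0.71 in the other splits, a narrow argument against chance tried after the results had been seen. Splits of 3 against 3 samples are too few to test: the real and highest other counts were 293 and 2497 in the fetus (3 of 10), 96 and 8 at 1 week (1 of 10), and 248 and 0 by limma at 4 weeks (1 of 10). Splits that called several times the real count point to a structure of the samples beyond tissue and housing. Among splits that part every pair, the real one called the most, with the others at most 664 at 8 weeks (of 32 splits), 1 in the fetus (of 4) and 14 in gnotobiotic mice (of 8).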

How the results depend on the processing

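The alternatives with the dyes as labelled, without the 12 opposing arrays, with the signs of the value table turned and with the scan day as a block were chosen after seeing the data. All others were chosen before. The cause of the changes below was not tested, except where fewer samples or terms show it. Here "tissue" stands for rectum against colon, "housing" for gnotobiotic against non-gnotobiotic mice, "tissue by" for the change of the tissue difference, and "age" for the step to that age. Only counts that changed by more than 1.5 times from those reported are given below. Beside a count of 0 from limma, the number at an unadjusted p under 0.05 is given as unadjusted. Samples are given by group and replicate.

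With the dyes as labelled, 11 of 12 counts changed so: tissue 8 weeks 915, tissue fetus 0 (176 unadjusted), tissue 1 week 0 (139 unadjusted), tissue 4 weeks 0 (816 unadjusted), tissue gnotobiotic 0 (365 unadjusted), housing rectum 1272, tissue by housing 0 (811 unadjusted), tissue by age 0 (1265 unadjusted), age 1 week 0 (537 unadjusted), age 4 weeks 828 and age 8 weeks 7718. 83 of 183 named calls were lost and 73 changed sign. Without the 12 opposing arrays, 6 of 12 counts changed so: tissue fetus 498, tissue 1 week 221, housing colon 260, housing rectum 225, age 4 weeks 3026 and age 8 weeks 1044. 40 of 183 named calls were lost. This left 1 sample in each fetal and 1-week group. With no dye term, 4 of 12 counts changed so: housing colon 1148, housing rectum 313, tissue by housing 14 and age 8 weeks 7047. 10 of 183 named calls were lost.

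With no background correction, 11 of 12 counts changed so: tissue fetus 706, tissue 1 week 297, tissue 4 weeks 499, tissue gnotobiotic 3140 (1021 higher), housing colon 1658, housing rectum 409, tissue by housing 329 (100 higher), tissue by age 1029, age 1 week 5008, age 4 weeks 3429 and age 8 weeks 1455. 1 of 183 named calls was lost. With Agilent's processed signals, 11 of 12 counts changed so: tissue fetus 635, tissue 1 week 587 (363 higher), tissue 4 weeks 673, tissue gnotobiotic 4019, housing colon 2998, housing rectum 1376, tissue by housing 787 (192 higher), tissue by age 915, age 1 week 4798, age 4 weeks 4344 and age 8 weeks 1652 (583 higher). 4 of 183 named calls were lost and 1 changed sign. With median centring in place of loess, 12 of 12 counts changed so: tissue 8 weeks 777 (492 higher), tissue fetus 99 (38 higher), tissue 1 week 11 (7 higher), tissue 4 weeks 28, tissue gnotobiotic 145 (105 higher), housing colon 41 (34 higher), housing rectum 24 (21 higher), tissue by housing 1 (1 higher), tissue by age 139 (120 higher), age 1 week 663 (62 higher), age 4 weeks 83 (64 higher) and age 8 weeks 56. 78 of 183 named calls were lost. With the value table as deposited, 11 of 12 counts changed so: tissue 8 weeks 365, tissue fetus 0 (140 unadjusted), tissue 1 week 0 (332 unadjusted), tissue 4 weeks 0 (668 unadjusted), tissue gnotobiotic 0 (543 unadjusted), housing colon 206 (164 higher), tissue by housing 1 (1 higher), tissue by age 0 (767 unadjusted), age 1 week 0 (337 unadjusted), age 4 weeks 179 (162 higher) and age 8 weeks 197 (48 higher). The share of higher genes also shifted by over 10 percentage points in housing rectum (139 of 149). 104 of 183 named calls were lost and 68 changed sign. With its signs turned, 11 of 12 counts changed so: tissue fetus 650, tissue 1 week 588 (362 higher), tissue 4 weeks 673, tissue gnotobiotic 4016, housing colon 3043, housing rectum 1444, tissue by housing 767 (183 higher), tissue by age 939, age 1 week 4778, age 4 weeks 4265 and age 8 weeks 1551 (427 higher). 4 of 183 named calls were lost and 1 changed sign. Median centring moved the median of all genes by over 0.1 in tissue fetus (to -0.143), tissue by age (to 0.180) and age 8 weeks (to -0.269). Quantile normalization of brightness between arrays left every ratio unchanged by construction and so tests nothing.

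With the compared groups alone, 7 of 11 counts changed so: tissue fetus 16, tissue 1 week 11, tissue 4 weeks 147, tissue gnotobiotic 331, housing colon 4, housing rectum 3 and tissue by housing 0 (1318 unadjusted). 72 of 172 named calls were lost. Age 8 weeks could not be estimated. Without replicate 6 of both tissues at 8 weeks, 3 of 12 counts changed so: housing colon 646, tissue by housing 84 and age 8 weeks 193. 3 of 183 named calls were lost. With a term for mucosa or whole organ, 3 of 12 counts changed so: housing colon 674, tissue by housing 100 and age 8 weeks 877. 5 of 183 named calls were lost. Without the gnotobiotic samples numbered 3, 2 of 9 counts changed so: tissue gnotobiotic 510 and tissue by housing 0 (831 unadjusted). 9 of 142 named calls were lost. Housing colon, housing rectum and age 8 weeks could not be estimated. With a term for stripped slides, 2 of 12 counts changed so: housing rectum 242 and tissue by housing 38. 3 of 183 named calls were lost. With stripped arrays alone tissue 8 weeks was 780, and with unstripped arrays alone 886, losing 6 and 4 of 28 named calls. With the mean of the probes of a gene, 1 of 12 counts changed so: housing colon 266. 16 of 183 named calls were lost. With no filter on dim probes, 0 of 12 counts did. 4 of 183 named calls were lost. With the stricter filter, 1 of 12 counts changed so: tissue by housing 15. 0 of 181 named calls were lost.

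With the replicate number as a block, tissue 8 weeks 3170, tissue fetus 528, tissue 1 week 173, tissue 4 weeks 500, tissue gnotobiotic 2573, housing colon 154, housing rectum 45, tissue by housing 461, tissue by age 1180, age 1 week 1327, age 4 weeks 565 and age 8 weeks 8. 30 of 183 named calls were lost. With the slide as a fixed block, 8 comparisons could be estimated, and tissue fetus 533, tissue 1 week 169, tissue 4 weeks 503, tissue gnotobiotic 2733, tissue by housing 483 and age 4 weeks 3099. 7 of 123 named calls were lost. With the slide as a random block (consensus correlation 0.520, against 0.441 for the pair), tissue fetus 614, tissue 1 week 233, tissue 4 weeks 565, tissue gnotobiotic 2573, housing colon 41, housing rectum 9, tissue by housing 331, tissue by age 781, age 1 week 1023 and age 8 weeks 1. 38 of 183 named calls were lost. With the scan day as a fixed block, for 8 comparisons, tissue 8 weeks 3049, tissue fetus 525, tissue 1 week 158, tissue 4 weeks 488, tissue gnotobiotic 2513, tissue by housing 223, tissue by age 937 and age 4 weeks 2748. 3 of 123 named calls were lost. These blocks could not estimate the other comparisons. At 1 week and 4 weeks the lowest correlations of same-numbered samples were 0.00312 and -0.0940, so they were not taken as pairs there. Elsewhere every such pair correlated above 0.1, yet some samples correlated more with another number, as in gnotobiotic pair 2 (0.323 against 0.645). Over all comparisons, 139 shifts of lists passed as reported, 25 with an estimated correlation, 107 with the dyes as labelled and 119 without the 12 arrays. In the 5 tissue comparisons 60 passed with the pair as a block, against 64 as reported.

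Leaving out each sample in turn gave these ranges: tissue 8 weeks 1396 to 1817, tissue fetus 135 to 495, tissue 1 week 60 to 98, tissue 4 weeks 147 to 239, tissue gnotobiotic 510 to 1452, housing colon 16 to 609, housing rectum 4 to 177, tissue by housing 0 to 146, tissue by age 224 to 524, age 1 week 1853 to 3655, age 4 weeks 886 to 1581 and age 8 weeks 49 to 163. Only samples of the groups compared were left out, so for age 8 weeks slide K, which fixed the dye term, stayed in. Tissue fetus changed without fetal colon 1 (135) and 3 (153) and rectum 1 (191), 2 (495) and 3 (182). Tissue 1 week changed without 1-week colon 1 (61) and rectum 1 (60). Tissue 4 weeks changed without 4-week colon 3 (147) and rectum 1 (162). Tissue gnotobiotic changed without gnotobiotic colon 3 or rectum 3 (510 each). Housing changed without gnotobiotic sample 3 of the tissue (colon 16, rectum 4), with that of the other kept. Tissue by housing changed without 8-week colon 1 (4), 2 (4), 3 (2), 4 (19), 5 (1) and 6 (146). It did without 8-week rectum 5 (4) and 6 (2). It did too without gnotobiotic colon 1 (4) and 3 (0) and rectum 2 (4), 3 (0) and 4 (28). Tissue by age changed without fetal colon 1 (224). Age 8 weeks changed without 4-week colon 3 (50), 8-week colon 6 (163), and 4-week rectum 2 (49) and 3 (51). Where limma called 0 genes, 831 had an unadjusted p under 0.05.

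Some named genes lost their call when any 1 of the samples given was left out, with the log2 differences in brackets. Tissue 8 weeks: without 8-week colon 5, 8-week rectum 1/2/6 (Gzma -2.45 to -2.30). Tissue fetus: without fetal colon 1 (Clca1 2.67), or without fetal colon 1/2/3, fetal rectum 1/3 (Cubn -4.00 to -2.88, Mylpf 1.89 to 2.58), or without fetal colon 2, fetal rectum 1/3 (Gcg -1.55 to -1.43), or without fetal colon 1/3, fetal rectum 1/3 (Hoxb13 2.50 to 2.85), or without fetal colon 1/3, fetal rectum 1/2 (Sval1 3.90 to 4.03). Tissue 1 week: without 1-week colon 2, 1-week rectum 1/2 (Cyp2c65 -3.66 to -3.37), or without 1-week colon 1, 1-week rectum 1 (Hoxb13 2.62 to 3.12). Housing colon: without gnotobiotic colon 3 (Ang4 -4.81, Aqp8 -2.89, Ccnb2 -2.06, Cyp2c55 -2.10, Cyp4f14 1.68, Dbp 3.35, Duoxa2 -2.83, Fabp4 2.08, Gstm1 -1.61, Mt1 2.79, Mt2 3.31, Neu1 1.501, Pcna -0.98, Retnlb -3.64), or without gnotobiotic colon 5 (Cdc20 -1.40), or without 8-week colon 1/2/5, gnotobiotic colon 3/5 (Pdk4 -3.54 to -2.27), or without 8-week colon 1/2, gnotobiotic colon 3 (Saa2 2.21 to 2.598). Housing rectum: without 8-week rectum 3/4, gnotobiotic rectum 3 (Birc5 -1.73 to -0.80), or without gnotobiotic rectum 3 (Ccnb2 -1.22, Cdc20 -0.65, Chd4 1.499, Crim1 1.20, Cyp2c55 -3.10, Cyp4f14 1.36, Mki67 -1.05, Plk1 -1.26, Selenom -1.44), or without 8-week rectum 1/3/4/6, gnotobiotic rectum 3 (Sord 1.38 to 1.55). Tissue by housing: without gnotobiotic colon 3, gnotobiotic rectum 3 (Aqp8 3.92), or without any of 10 samples (Casp6 0.95 to 1.12), or without 8-week colon 3/5, gnotobiotic colon 3, gnotobiotic rectum 3 (Deptor -1.20 to -1.04), or without any of 14 samples (Evpl -1.04 to -0.88), or without 8-week colon 5, gnotobiotic colon 1/3, 8-week rectum 6, gnotobiotic rectum 3 (Gsdmc 1.93 to 2.13), or without any of 14 samples (Gsdmc3 1.75 to 2.03), or without any of 10 samples (Hmga1 -1.36 to -0.89), or without any of 14 samples (Oip5os1 -1.12 to -0.93), or without 8-week colon 3/5, gnotobiotic colon 3, 8-week rectum 6, gnotobiotic rectum 2/3 (Sdhb 1.17 to 1.47). Tissue by age: without fetal colon 1/3, fetal rectum 3 (Apoa4 2.22 to 2.42), or without fetal colon 1, fetal rectum 1/3 (Krt1 -2.45 to -2.20), or without fetal colon 1, fetal rectum 3 (Neu1 0.97 to 1.39). Age 1 week: without 1-week colon 1, fetal colon 1, 1-week rectum 1, fetal rectum 1 (Des 1.76 to 1.91). Age 4 weeks: without any of 7 samples (Dlk1 -1.48 to -1.08), or without 4-week colon 2 (Mest -1.65). Age 8 weeks: without any of 10 samples (Actg2 -2.48 to -2.35), or without any of 13 samples (Ccnb2 1.53 to 1.62), or without any of 11 samples (Cpe -2.83 to -2.62), or without 4-week colon 3, 4-week rectum 2/3 (Rpl31 1.08 to 1.16), or without 4-week colon 1/3, 4-week rectum 2/3 (Tpm2 -3.73 to -3.57).

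With the dyes as labelled, 73 differences of named genes changed sign. Tissue fetus: Amn 0.31, Best2 -1.32, Cdx2 0.80, Clca1 -1.31, Cubn 0.16, Fabp2 0.40, Gcg 0.34, Hoxb13 -0.083, Krt1 -1.36, Krtdap -0.091, Lor -1.35, Ly6d -0.40, Meltf 0.89, Myh3 -1.09, Mylpf -0.32, Sct 0.82 and Sval1 -1.78. Tissue 1 week: Atp12a -0.61, Best2 -0.62, Cdx2 0.95, Cyp2c65 0.74, Isx 0.52, Krt5 -0.068, Lor -0.26, Saa1 -0.72 and Sct 0.96. Tissue gnotobiotic: Aqp8 -0.29, Cdx2 0.42, Fabp4 0.26 and Sct 0.13. Housing colon: Ang4 4.18, Ccnb2 0.19, Dbp -0.093, Duoxa2 2.10, Gsdmc 2.31, Gsdmc3 1.56, Mt1 -1.46, Mt2 -1.503, Neu1 -1.07, Pcna 0.37 and Retnlb 3.13. Housing rectum: Cyp2c55 1.73 and Selenom 0.15. Tissue by housing: Aqp8 -0.47 and Gsdmc -0.38. Tissue by age: Apoa4 -0.026, Clca1 0.50, Glb1 -0.86, Krt1 1.90, Ly6d 0.14 and Neu1 -0.66. Age 1 week: Afp 1.86, Alas2 1.41, Aqp8 -1.11, Cd74 -0.36, Ctss -0.98, Cyp2c65 -0.021, Des -0.36, Dmbt1 -1.03, Fabp1 0.84, Fgg 0.65, Klk1 -0.57, Meg3 0.78, Mki67 0.39, Mylpf 0.40, Nqo1 -0.44, S100a9 0.35, Slc25a37 1.501, Slc4a1 0.90 and Slc9a2 -0.32. Age 4 weeks: Col3a1 1.24 and Postn 1.11. Age 8 weeks: Ccnb2 -0.22. With the value table as deposited, 68 differences of named genes changed sign. Tissue fetus: Amn 1.17, Apoa4 0.45, Best2 -1.87, Cdx2 1.40, Clca1 -1.51, Cubn 1.47, Gcg 0.76, Hoxb13 -0.66, Krt1 -0.60, Lor -0.71, Ly6d -1.05, Meltf 0.53, Myh3 -0.17, Sct 0.88 and Sval1 -1.98. Tissue 1 week: Atp12a -1.52, Best2 -0.64, Cdx2 1.64, Cyp2c65 1.36, Hoxb13 -0.93, Isx 1.19, Krt5 -0.74, Lor -0.37, Saa1 -0.81 and Sct 1.05. Tissue by age: Clca1 0.91, Glb1 -1.02, Krt1 2.48, Ly6d 1.12 and Neu1 -0.47. Age 1 week: Afp 2.09, Alas2 0.73, Aqp8 -1.04, Cd74 -0.34, Ctss -0.87, Cyp2c65 -1.49, Des -0.49, Dmbt1 -0.95, Fabp1 1.82, Fgg 0.16, Klk1 -0.67, Meg3 0.81, Mki67 0.54, Mylpf 0.76, Nqo1 -0.92, S100a9 0.46, Slc25a37 1.93, Slc4a1 0.53 and Slc9a2 -0.93. Age 4 weeks: Car1 -1.05, Car4 -0.20, Clca1 -3.67, Col3a1 1.97, Col5a1 1.49, Cyp2c55 -0.079, Dlk1 3.96, Grb10 1.64, Krt20 -1.46, Mdk 1.91, Mest 3.39, Muc2 -1.99, Pigr -1.06, Postn 0.70, Psmb8 -1.498, Sectm1b -0.48, Sult1a1 -0.63 and Zg16 -0.66. Age 8 weeks: Dcn 0.98. Elsewhere Krt1 in tissue by age turned to 0.50 with Agilent's processed signals and with the signs of the value table turned.

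Genes not well above background cannot be told from absent, and a ratio against a dim reference is imprecise. Groups of 3 samples limit the fetal, 1-week and 4-week comparisons.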

Other observations

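The overlaps below were computed after the comparisons had been seen. Across the 5 comparisons of rectum with colon, 7 genes were called higher in rectum in every one: Atp2c2, Best2, Hoxb13, Lrmp, Mfsd4a, Ndrg2 and S100a14. Hoxb13, a posterior patterning gene, ranged over log2 differences of 2.84 to 4.28, and the channel gene Best2 over 2.30 to 3.72. 10 genes were called lower in every one: Cdx2, Gcg, Golt1a, Neu1, Nr1h4, Prap1, Sct, Slc51a, St3gal1 and Ugt1a6b. Cdx2, the intestinal transcription factor, ranged over -3.35 to -4.58, the hormone genes Sct over -3.21 to -4.02 and Gcg, which encodes proglucagon, over -1.41 to -3.10, and the bile acid receptor Nr1h4 over -0.98 to -2.03. 29 genes were called higher at 1 stage and lower at another.

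Stages shared more calls in the same direction than independent lists would. These comparisons share no samples but share the dye term and the estimate of the spread. The 8-week and gnotobiotic comparisons shared 274 (expected 17.6) higher and 360 (expected 29.3) lower genes. The 8-week and 4-week comparisons shared 117 (expected 3.99) higher and 120 (expected 5.07) lower.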
